A study of Mus musculus with 6 samples.

How the data were processed

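The samples were 3 cultures of macrophages from E-FABP (Fabp5) knockout mice and 3 from wild-type mice, both described as C57BL/6. Per the labels' protocols, bone marrow cells were grown for 7 days with GM-CSF at 20 ng/ml in dishes of 100 mm, replated in 12-well plates, and kept with E0771 tumour cells in an insert for 18 h before total RNA was taken. Biotin-labelled cRNA was made with a 3' IVT kit and hybridised to Affymetrix arrays, per the labels' protocols.

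The deposited table holds log2 values, 1 per probe set and array, for 45101 probe sets and the 6 arrays; the log2 scale was read from the range of the values. The submitters' processing notes name affy 1.36.1, limma 3.14.4, GCRMA 2.30.0 and RMA, without a role or an order, so whether GCRMA or RMA made these values is not given in the sources used here. Both methods summarise the probes of a set on the log2 scale after background correction and quantile normalization, which makes the arrays' distributions alike and would hide a change of most genes in the same direction. They differ in how far low intensities are pulled down, so fold changes of dim probe sets depend on which was used. Scanner intensities and detection calls were not used here.

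The 64 Affymetrix control probe sets were left out, and 45037 probe sets were tested with no filter on dim ones. Gene names came from the platform's annotation, with symbols updated through gene identifiers in a RefSeq table. Of the probe sets tested, 34945 had 1 gene, 932 had several and 9160 were unnamed here. Probe sets with several genes or none were tested but not named. For values per gene, the probe set with the highest mean over the 6 arrays stood for its gene, which gave 18193 genes; the probe sets of a gene can disagree. No genome build is tied to the deposited values, so no coordinates are given, and the RefSeq table served only for names and for which genes neighbour each other. A list member without a probe set of its own was not analysed here.

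Knockout was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the sole term), with Benjamini-Hochberg adjustment over all 45037 probe sets and a threshold of 0.05. Fold changes are knockout minus wild type on the log2 scale. A test that permutes the 6 arrays could not give a two-sided p under 0.1. Adjusted p-values and SEs of genes are limma's, from variances moderated by eBayes. The 19 gene lists and 12 marker lists were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01, against all other genes, with adjustment over the 31 lists. Camera with an estimated correlation and fry were alternatives; fry's directional p asks whether a list's genes move one way on balance, and does not compare the list with other genes. Camera called 17 of the 31 lists, 11 lower and 6 higher. With an estimated correlation it called 0, with 4 lists at an unadjusted p under 0.05 and a lowest adjusted p of 0.15. That lowest value was the fibroblast list's, whose estimated correlation (-0.02) lay under the preset 0.01. The loss of calls in this setting is therefore not due to correlation among genes alone. Fry called 6, of which 3 were lower and 3 higher.

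The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Fabp5, Fabp4 and Ifnb1 always. It took the 12 largest rises and the 12 largest falls among genes past the threshold whose genotypes did not overlap and whose higher mean was above 5.63, the median of all values, leaving out predicted genes without a symbol. From each list described it took up to 4 members with the smallest p. Genes chosen after their values were seen are named as such.

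The alternatives were quantile normalization and median centring of the deposited values, probe sets above the median level only, a floor at the 20th percentile (4.07), eBayes with trend and robust settings, array weights, the replicate number as a block, leaving out probe sets that end in _s_at or _x_at, the mean of a gene's probe sets, leaving out each array in turn, an absolute log2 fold change of at least 1, and an adjusted p under 0.1. The fit was tested on simulated arrays with the real probe sets' means and spreads, in which 200 of 45037 probe sets were changed. It recovered 52.2% of changes of 0.5, 85.1% of changes of 1 and 100% of changes of 2 on the log2 scale, with 8 false calls. The set test called 0 of 31 lists on simulated arrays without changes, and called the interferon-stimulated list when it was lowered by 0.5. These simulated genes vary independently, which real genes need not do. No array held the same values as another. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.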

Results

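Gene expression was measured on 6 Affymetrix 3' expression arrays, 3 from E-FABP knockout and 3 from wild-type mouse macrophages. E-FABP, the epidermal fatty-acid-binding protein, is a cytosolic lipid carrier encoded by Fabp5. The cells were bone marrow macrophages grown with the growth factor GM-CSF, a culture that also holds cells with dendritic cell features. All 6 samples had then been kept for 18 h with E0771 cells, a mouse breast cancer line, held apart in a culture insert. The comparison therefore asks how tumour-exposed macrophages without E-FABP differ from tumour-exposed wild-type macrophages, and the effect of the tumour cells themselves was not analysed here. The labels call the samples of a genotype biological replicates without saying whether each came from its own animal, so p-values speak of these samples only. Each gene's SE and p-value rest on its own spread over the arrays and on a prior from all probe sets (limma's prior degrees of freedom 5.04). For genes with a wide spread, the SE is therefore smaller than their own spread would give. The median log2 intensity of an array lay between 5.60 and 5.64, and the SD over probe sets between 2.35 and 2.38. Pearson's r across probe sets, which are not independent replicates, was 0.9965 to 0.9977 within a genotype and 0.9914 to 0.9961 between genotypes. The number of arrays, 3 per genotype, limits the precision of every value.

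Fabp5, the targeted gene, was nearly lost in the knockout. Its brighter probe set read 8.27 ± 0.13 (log2 intensity, mean ± SD, n = 3) in knockout and 14.44 ± 0.03 (n = 3) in wild type, a difference of -6.17 with an SE of 0.08, or 72.0-fold (limma adjusted p = 1.9568e-09). The other probe set read 6.01 ± 0.35 against 13.90 ± 0.06 (n = 3 each; limma adjusted p = 3.0728e-08). Since 6.01 is close to the median of all values (5.63) and no background level was available here, its fall may be a lower bound. Each of the 3 arrays from knockout cells thus carried its stated genotype, although which part of the gene was deleted, and whether the probes lie in it, is not given in the sources used here. Fabp4, which codes for the adipocyte fatty-acid-binding protein and neighbours Fabp5 on chromosome 3, fell by 1.08 (SE 0.11, n = 3 per genotype, limma adjusted p = 0.00811), and its other probe sets lay -0.84, -0.70 and -0.93 from wild type. Whether probes for Fabp4 also bind the related Fabp5 transcript was not tested.

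**Figure D1:**
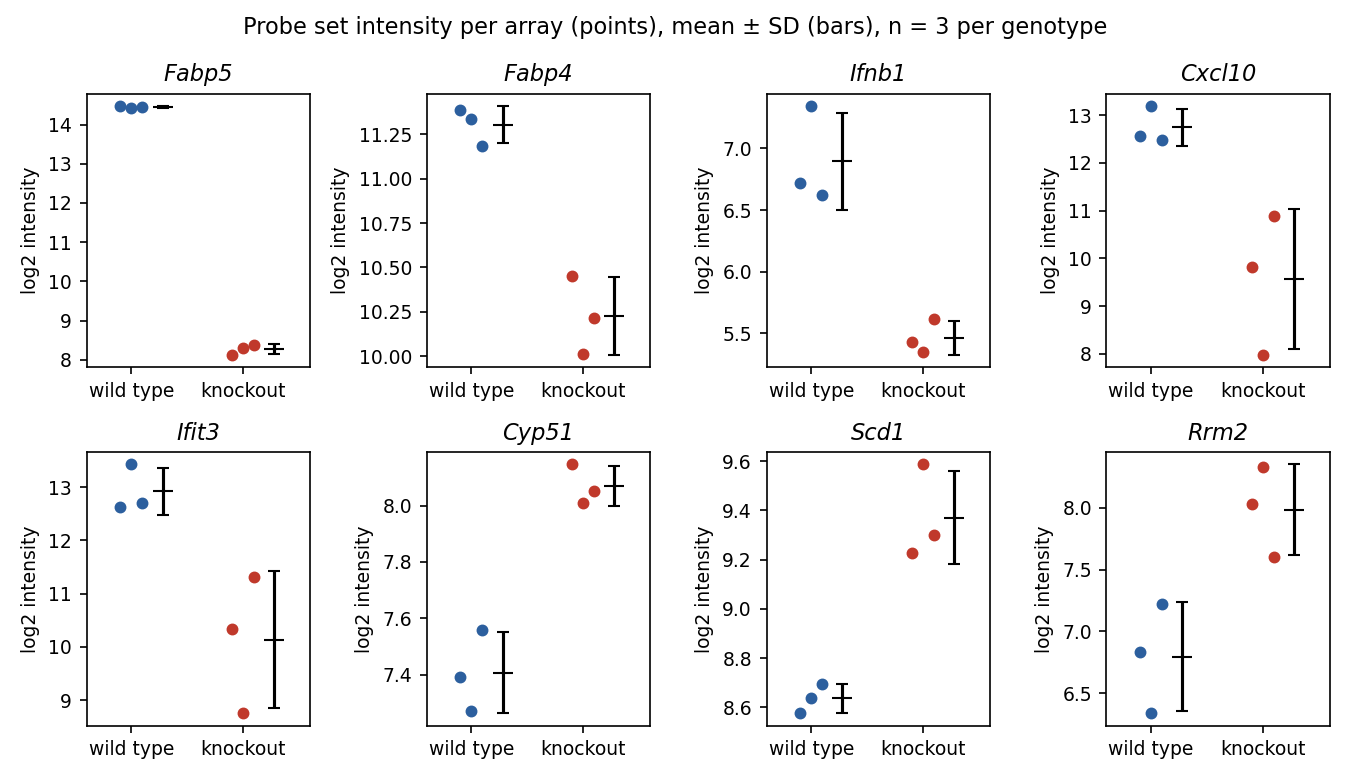
Log2 intensity of 8 genes (1 panel each) on every array, with wild type in blue, knockout in red and bars for the mean ± SD of the 3 arrays of a genotype. The genotypes are apart in every panel, from 14.44 against 8.27 for Fabp5 to 7.41 against 8.07 for Cyp51, and the knockout arrays are spread widely for Cxcl10 (SD 1.47) and Ifit3 (SD 1.29).

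With both Fabp5 probe sets counted, 927 probe sets were higher and 764 lower in knockout at a limma adjusted p under 0.05, out of 45037 tested. The falls were the larger changes: 157 probe sets fell by at least 1 on the log2 scale, against 14 that rose by as much. With 1 probe set for each of 18193 genes, 519 genes were higher and 373 lower. The 3 values of a genotype did not overlap those of the other for 31.9% of genes, where chance gives 10% for a single gene. Genes are not independent of each other, so the distance between these shares is not a test of genotype. The number of called probe sets, 1691, fell to 40 without knockout replicate 1, 104 without wild-type replicate 2, 326 without knockout replicate 2, 343 without wild-type replicate 1 and 953 without wild-type replicate 3, and was 1360 without knockout replicate 3. Among the 75 called genes other than Fabp5 that the fixed rule names, without those chosen after their values were seen, 72 lost the call without knockout replicate 1 and 68 without wild-type replicate 2, while none changed direction in any of these fits.

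Genes induced by type I interferon, the antiviral cytokine family of interferon alpha and beta, fell together in the knockout cultures. Of 39 measured genes of this fixed list, 33 fell, 0 rose and 6 did not pass; adjusted over the list alone, 38 fell. All 39 had a lower mean in knockout, and in 37 the 3 knockout values lay below the 3 wild-type values. The median change was -1.07, or 2.09-fold (limma's camera, adjusted p = 1.0424e-29 with a preset correlation of 0.01; adjusted p = 0.292 with an estimated correlation of 0.90). Cxcl10, a chemokine that attracts T cells, fell from 12.75 ± 0.39 to 9.56 ± 1.47 (n = 3 each), a change of -3.18 (SE 0.59, limma adjusted p = 0.0266). The antiviral RNA-binding proteins fell as well, Ifit3 (-2.78, SE 0.53), Ifit2 (-2.44, SE 0.47) and Ifit1 (-2.23, SE 0.44). So did Oasl1 (-2.36, SE 0.31), Cmpk2 (-2.52, SE 0.48), the RNA exonuclease Isg20 (-2.28, SE 0.38), the influenza-resistance GTPase Mx1 (-2.13, SE 0.31), Herc6 (-1.40, SE 0.20) and the signal transducer Stat2 (-1.27, SE 0.17), each with a limma adjusted p between 0.0158 and 0.0310. The 12 largest falls also held Ifit1bl1 (-2.97, SE 0.51), Ms4a4c (-2.83, SE 0.47) and Ifi213 (-2.71, SE 0.48), which stand on no fixed list. The number of list members past the threshold was 0 without knockout replicate 1 or wild-type replicate 2, 8 without wild-type replicate 1, 15 without wild-type replicate 3, 23 without knockout replicate 2 and 36 without knockout replicate 3, and all 39 means stayed lower each time. The 11 largest falls after Fabp5 had limma adjusted p of 0.0648 to 0.0921 without knockout replicate 1 and of 0.0563 to 0.121 without wild-type replicate 2. On the same arrays dendritic cell markers were higher (median 0.29), and neutrophil (median -0.48) and fibroblast markers (median -0.29) were lower. Knockout replicates 1, 2 and 3 lay at -0.57, -1.21 and -0.14 from the gene means for the interferon-stimulated list and at -0.18, -0.56 and 0.03 for the neutrophil list. Wild-type replicates 1, 2 and 3 lay at 0.55, 0.87 and 0.50 for the first list and at 0.23, 0.12 and 0.36 for the second. The interferon-stimulated and neutrophil lists thus ran the same way among the knockout arrays and not among the wild-type arrays. Dendritic cell markers lay at 0.11, 0.34 and 0.01 on knockout replicates 1, 2 and 3. On wild-type replicates 1, 2 and 3 they lay at -0.19, -0.23 and -0.04. Their order was the inverse of that of the interferon-stimulated list in both genotypes, as was that of the cell cycle list.

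Ifnb1, the gene of interferon beta itself, was lower in knockout. It read 5.46 ± 0.14 against 6.90 ± 0.39 in wild type (n = 3 each), a change of -1.43 (SE 0.17, limma adjusted p = 0.0136; 0.0631 without knockout replicate 1). Its knockout mean lies under 5.63, the median of all values, so the size of this fall may be a lower bound. Among 20 measured interferon genes, sensors and signalling genes, 5 fell, 0 rose and 15 did not pass, and adjusted over the list alone 10 fell and 4 rose. The other 4 that fell were the double-stranded RNA receptor Tlr3 (-1.79, SE 0.32), the DNA sensor Cgas (-0.57, SE 0.09), the receptor chain Ifnar1 (-0.41, SE 0.08) and the adaptor Myd88 (-0.51, SE 0.11). The list's median was -0.18 (camera adjusted p = 0.00305; adjusted p = 0.292 with an estimated correlation). The number that fell was 0 without knockout replicate 1, 1 without wild-type replicate 1 or wild-type replicate 2, 2 without knockout replicate 2 and 3 without wild-type replicate 3.

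The GTPases and chemokines typical of interferon gamma, which type I interferon can also induce, fell by a similar amount. Of 16 measured, 13 fell, 0 rose and 3 did not pass, and adjusted over the list alone 14 fell and 1 rose. The median was -1.07 (camera adjusted p = 1.0088e-13; adjusted p = 0.292 with an estimated correlation). Iigp1, a GTPase that acts on the vacuoles of intracellular parasites, fell by 2.74 (SE 0.36). Gbp3 (-1.45, SE 0.20), the signalling inhibitor Socs1 (-0.69, SE 0.10) and Cd274, which codes for the checkpoint ligand PD-L1 (-0.66, SE 0.08), fell too. The number that fell was 0 without knockout replicate 1, 1 without wild-type replicate 2 and 8 without wild-type replicate 1. The neutrophil and fibroblast markers were lower on these arrays as well (medians -0.48 and -0.29), and dendritic cell markers higher (0.29). In the list for MHC and antigen presentation, 5 of 17 fell, 0 rose and 12 did not pass (adjusted over the list alone, 7 fell and 2 rose; median -0.12, camera adjusted p = 0.0082; adjusted p = 0.292 with an estimated correlation). All 5 serve the MHC class I pathway: the regulator Nlrc5 (-1.19, SE 0.19), the peptide transporter Tap1 (-0.80, SE 0.12), its partner Tapbp (-0.59, SE 0.09) and the immunoproteasome subunits Psmb9 (-0.56, SE 0.12) and Psmb10 (-0.50, SE 0.10). That number was 0 without knockout replicate 1, wild-type replicate 1 or wild-type replicate 2, 2 without knockout replicate 2 and 3 without wild-type replicate 3.

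Inflammatory cytokines and M1 markers, the genes of classically activated macrophages, were lower in knockout as a group. Of 28 measured, 6 fell, 0 rose and 22 did not pass, and adjusted over the list alone 14 fell and 2 rose. The 2 that rose, Il12b (0.62, SE 0.15) and Cd80 (0.40, SE 0.13), lie outside the rule for named genes and were chosen after their values were seen. The median was -0.33 (camera adjusted p = 1.1529e-08; adjusted p = 0.292 with an estimated correlation). The costimulatory genes Cd40 (-0.76, SE 0.11) and Cd86 (-0.68, SE 0.11) and the chemokines Ccl4 (-0.74, SE 0.14) and Ccl7 (-0.69, SE 0.13) fell, with limma adjusted p between 0.0164 and 0.0275. The number that fell was 0 without knockout replicate 1 or wild-type replicate 2, 1 without knockout replicate 2 or wild-type replicate 1, 3 without wild-type replicate 3 and 9 without knockout replicate 3. Neutrophil markers were lower on the same arrays (median -0.48, camera adjusted p = 2.5647e-05; adjusted p = 0.357 with an estimated correlation). Of these 13 markers 0 passed limma's threshold, with 10 lower and 1 higher at an unadjusted p under 0.05. Knockout replicate 2 was the lowest array in the inflammatory and the neutrophil list (-0.37 and -0.56). Fibroblast markers were lower too (median -0.29), and dendritic cell markers higher (median 0.29). Markers of M2 and tumour-associated macrophages did not pass as a list (camera adjusted p = 0.625). Their mean deviation was 0.03 to 0.06 on the knockout arrays and -0.06 to -0.04 on the wild-type arrays. The median of these 24 markers was 0.01. Of these, Pdcd1lg2, which codes for PD-L2 (0.60, SE 0.14), and Myc (0.39, SE 0.08) rose, a number that was 0 without knockout replicate 1, knockout replicate 2, wild-type replicate 1 or wild-type replicate 2, and 22 did not pass (adjusted over the list alone, 5 rose and 3 fell).

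**Figure D2:**
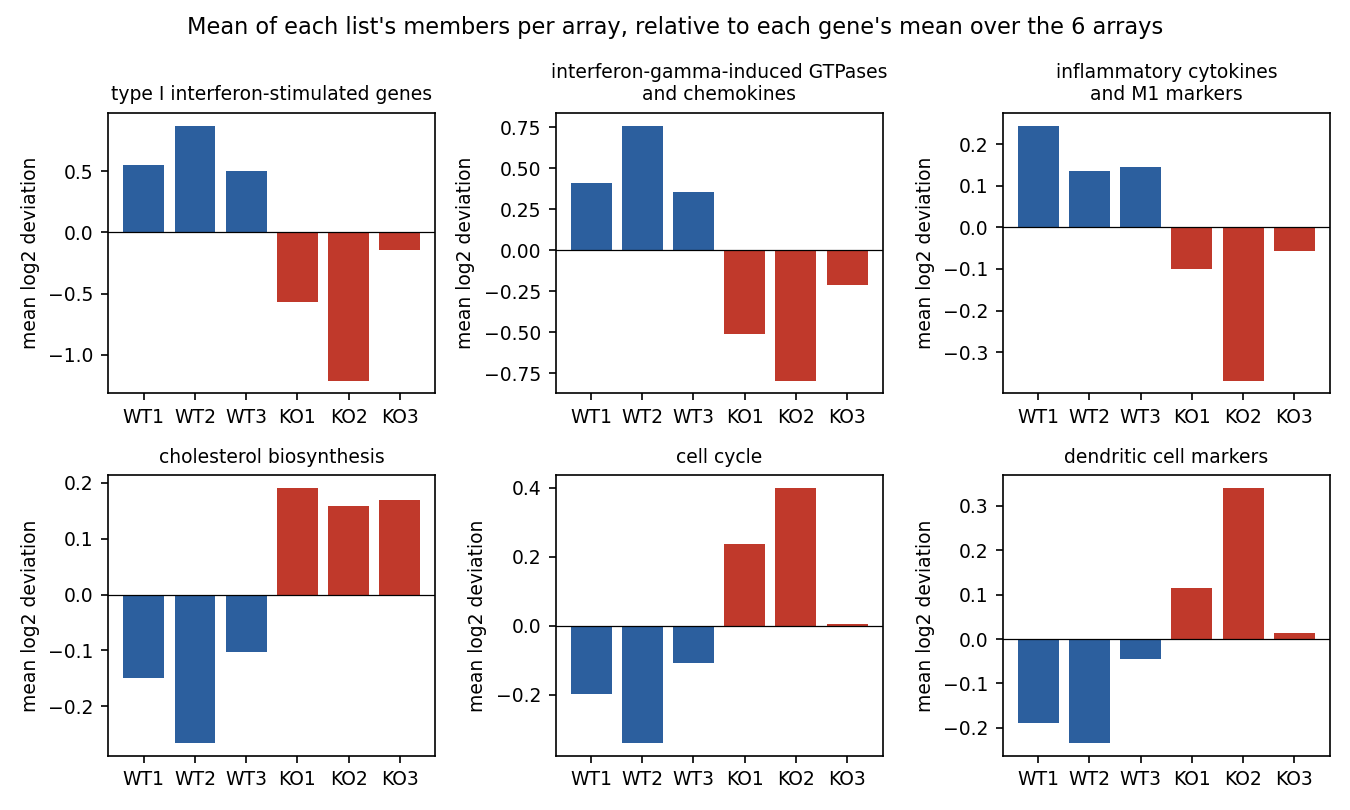
Mean log2 deviation of the members of 6 lists from each gene's mean over the 6 arrays, per array, with wild type in blue and knockout in red. In every panel the knockout bars lie on the other side of the wild-type bars; knockout replicate 2 has the lowest interferon-stimulated genes (-1.21) and the highest dendritic cell markers (0.34), and the cell cycle list of knockout replicate 3 is near 0 (0.01).

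Genes of cholesterol and fatty acid synthesis rose in the knockout cultures. Of 21 measured cholesterol synthesis genes, 10 rose, 0 fell and 11 did not pass; adjusted over the list alone, 16 rose. The median was 0.33 (camera adjusted p = 1.7711e-10; adjusted p = 0.292 with an estimated correlation). The sterol carrier gene Stard4 rose by 0.71 (SE 0.08), and the synthesis enzymes Cyp51 by 0.66 (SE 0.09), Idi1 by 0.66 (SE 0.09) and Sqle, which acts at a rate-limiting step, by 0.47 (SE 0.07), with limma adjusted p between 0.0127 and 0.0169. In the list for fatty acid synthesis and desaturation, 5 of 17 rose, 0 fell and 12 did not pass (adjusted over the list alone, 9 rose; median 0.21, camera adjusted p = 1.3473e-04; adjusted p = 0.292 with an estimated correlation). The desaturases Scd2 (0.77, SE 0.14), Scd1 (0.74, SE 0.10) and Fads1 (0.48, SE 0.08), the elongase Elovl5 (0.47, SE 0.09) and the fatty acid synthase Fasn (0.44, SE 0.09) were the 5. Without knockout replicate 1 both numbers were 0 and without wild-type replicate 2 both were 1; the cholesterol number was 5 without wild-type replicate 1 and 6 without knockout replicate 2, and the fatty acid number 2 and 1. Dendritic cell markers (median 0.29) were higher, and neutrophil (-0.48) and fibroblast markers (-0.29) lower, on the arrays with these rises, and RNA was taken from the whole culture. Myd88, Psmb9 and Fasn lie outside the rule for named genes and were chosen after their values were seen.

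Smaller shifts were seen in other lipid and energy lists, on the arrays with the dendritic, neutrophil and fibroblast marker shifts given above. Among 23 genes of PPAR targets and fatty acid oxidation, Hadh (0.55, SE 0.09), Acot1 (0.50, SE 0.06) and Acadm (0.39, SE 0.07), enzymes that handle fatty acyl-CoA, rose, 0 fell and 20 did not pass. That list's median was 0.11 (camera adjusted p = 0.0116; 0.0588 without wild-type replicate 2; adjusted p = 0.414 with an estimated correlation), 8 rose and 2 fell adjusted over the list alone, and the number that rose was 0 without knockout replicate 1 or wild-type replicate 2 and 1 without wild-type replicate 1. Oxidative phosphorylation genes were higher by a median of 0.13 (camera adjusted p = 1.1702e-04; adjusted p = 0.407 with an estimated correlation). Of its 24 genes 0 passed limma's threshold by themselves, 9 were higher at an unadjusted p under 0.05 and 5 rose adjusted over the list alone. With trend and robust settings 7 rose, with the mean of a gene's probe sets 5 and with above-median probe sets only 3. After quantile normalization or median centring 0 rose. In the list for lipid droplets, fatty acid uptake and lipolysis, Fabp4 and the heart-type Fabp3 (-1.10, SE 0.13) fell, 0 rose and 25 of 27 did not pass (adjusted over the list alone, 6 fell and 2 rose). Whether Fabp3 probes also bind Fabp5 was not tested. Its median was -0.06 (camera adjusted p = 0.0366; adjusted p = 0.414 with an estimated correlation), and camera's adjusted p was 0.106 without knockout replicate 1, 0.124 without knockout replicate 2, 0.0565 without wild-type replicate 1 and 0.0584 without wild-type replicate 3. The replicate block gave this list a camera adjusted p of 0.0651, and the mean of a gene's probe sets 0.0507. Without knockout replicate 1 or wild-type replicate 2, 1 of its members fell. The list of LXR targets and cholesterol efflux was lower by a median of -0.10 (camera adjusted p = 0.0366; 0.0626 without knockout replicate 1 and 0.112 without wild-type replicate 3; adjusted p = 0.292 with an estimated correlation). The mean of a gene's probe sets gave a camera adjusted p of 0.0727 for this list. Its only member past the threshold went the other way: Scarb1, a receptor for high-density lipoprotein, rose by 0.37 (SE 0.07), and 13 of 14 did not pass (adjusted over the list alone, 1 rose and 2 fell). Scarb1 lost its call without each array in turn (limma adjusted p of 0.0578 to 0.101).

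Cell cycle genes rose in the knockout cultures. Of 25 measured, 11 rose, 0 fell and 14 did not pass; adjusted over the list alone, 16 rose. The median was 0.48 (camera adjusted p = 9.4316e-07; adjusted p = 0.414 with an estimated correlation). Rrm2, the ribonucleotide reductase subunit that supplies DNA precursors, rose from 6.79 ± 0.44 to 7.98 ± 0.37 (n = 3 each), a change of 1.19 (SE 0.23, limma adjusted p = 0.0295). The replication helicase subunits Mcm3 (0.71, SE 0.11) and Mcm4 (0.68, SE 0.11) and the mitotic ubiquitin-conjugating enzyme Ube2c (0.58, SE 0.11) rose as well. The number that rose was 0 without knockout replicate 1, knockout replicate 2, wild-type replicate 1 or wild-type replicate 2, 4 without wild-type replicate 3 and 13 without knockout replicate 3. It was 6 after quantile normalization, 13 after median centring, and 0 with the replicate block or the floor. Dendritic cell markers, whose median was 0.29, were higher on the same arrays, and neutrophil (-0.48) and fibroblast markers (-0.29) were lower.

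The largest single rise was that of Lrmda, a melanocyte differentiation gene, from 5.82 ± 0.20 to 8.18 ± 0.40 (n = 3 each), a rise of 2.37 (limma adjusted p = 0.00278). The size of this rise may be a lower bound, since the wild-type mean is close to the median of all values. Besides Lrmda and Rrm2, the 12 largest rises were those of Tmem267 (1.28, SE 0.24), the transcription factor Sox4 (1.14, SE 0.22), Nrep (1.12, SE 0.20), the glycosyltransferase Galnt12 (1.04, SE 0.19), the chromatin remodeller Hells (1.02, SE 0.19), the lectin receptor Klrd1 (0.97, SE 0.22), the MHC class II chaperone gene H2-DMb2 (0.97, SE 0.19), Rnf180 (0.95, SE 0.14), the sialic acid receptor Siglecf (0.95, SE 0.14) and Strip2 (0.94, SE 0.17). Their limma adjusted p lay between 0.0177 and 0.0481. The wild-type means of Klrd1 (5.00) and Galnt12 (6.03) also lie under or near that median, so the sizes of their rises may be lower bounds. Lrmda passed without each array in turn (limma adjusted p at most 0.0369). The other 11 did not pass without knockout replicate 1 (limma adjusted p of 0.0595 to 0.102) or without wild-type replicate 2 (0.0546 to 0.144), and 3 of them passed without knockout replicate 2 or wild-type replicate 1.

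Markers of the macrophages themselves moved little. The median of 13 macrophage markers was -0.08 (camera adjusted p = 0.0443; adjusted p = 0.437 with an estimated correlation), and camera's adjusted p was 0.198 without knockout replicate 2, 0.0745 without wild-type replicate 2, 0.0543 without wild-type replicate 3 and 0.0576 after quantile normalization. Camera's adjusted p was also 0.0690 with the floor, 0.0523 with array weights and 0.0727 with the mean of a gene's probe sets. The Fc receptor Fcgr1 (-1.13, SE 0.19) and the phagocytic receptor Mertk (-0.46, SE 0.08) fell, 0 rose and 11 did not pass, the same adjusted over the list alone; this number was 0 without knockout replicate 1, wild-type replicate 1 or wild-type replicate 2 and 1 without knockout replicate 2. Both genes also stand in the list for lysosome and phagocytosis, in which 0 rose and 21 of 23 did not pass (3 fell adjusted over the list alone; median -0.04, camera adjusted p = 0.0163; 0.0557 without knockout replicate 2; adjusted p = 0.414 with an estimated correlation).

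Markers of other cell types moved in different directions. Dendritic cell markers were higher (median 0.29 over 13 genes, camera adjusted p = 0.00305; adjusted p = 0.414 with an estimated correlation): Fscn1, an actin-bundling protein of mature dendritic cells (0.55, SE 0.12), and the transcription factor Batf3 (0.53, SE 0.11) rose, 0 fell, 11 did not pass, and adjusted over the list alone 6 rose. The number that rose was 0 without knockout replicate 1, knockout replicate 2, wild-type replicate 1 or wild-type replicate 2, 3 without wild-type replicate 3 and 4 without knockout replicate 3. Neutrophil and granulocyte precursor markers were lower (median -0.48 over 13 genes, camera adjusted p = 2.5647e-05; adjusted p = 0.357 with an estimated correlation). Of these, 0 passed limma's threshold by themselves, 10 were lower and 1 higher at an unadjusted p under 0.05, the same as adjusted over the list alone, and 7 fell without knockout replicate 3. The granule genes Camp (-1.03, SE 0.28) and Ngp (-0.92, SE 0.24) were among the 10. Fibroblast and stroma markers were lower (median -0.29 over 12 genes, camera adjusted p = 5.2416e-07; adjusted p = 0.15 with an estimated correlation). The collagen gene Col1a2 (-1.29, SE 0.11), the proteoglycan gene Dcn (-1.10, SE 0.14), Col3a1 (-0.48, SE 0.08) and Acta2 (-0.38, SE 0.08) fell, 0 rose, 8 did not pass, and adjusted over the list alone 7 fell. The first 3 have knockout means near or under the median of all values, so the sizes of their falls may be lower bounds. That number was 1 without knockout replicate 1 or wild-type replicate 2 and 2 without knockout replicate 2 or wild-type replicate 1.

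The other marker lists did not pass with camera in the planned fit of all probe sets. Monocyte markers had a median of -0.09 over 7 genes (adjusted p = 0.306; 0.0321 without knockout replicate 3), with 0 genes past limma's threshold, 2 lower at an unadjusted p under 0.05 and 2 that fell adjusted over the list alone. Of 7 eosinophil markers, Siglecf rose, as it did adjusted over the list alone (list median -0.17, mean 0.02, direction lower in camera, adjusted p = 0.277). Of 11 mast cell and basophil markers, the histidine decarboxylase gene Hdc fell by 0.40 (SE 0.07; median -0.03, mean 0.01, direction lower in camera, adjusted p = 0.487; adjusted over the list alone, 1 rose and 1 fell). Of 10 B cell markers, the adaptor gene Blnk fell by 0.39 (SE 0.07; median -0.02, adjusted p = 0.151; median -0.21 over 4 genes, adjusted p = 0.0187 with above-median probe sets only; 2 fell adjusted over the list alone). Siglecf lost its call without knockout replicate 1 (limma adjusted p = 0.0718) or wild-type replicate 2 (0.0744), Hdc without each of the 6 arrays in turn, and Blnk without each except wild-type replicate 3. No gene passed limma's threshold among 8 T and NK cell markers (median -0.08, adjusted p = 0.109), 10 erythroid and megakaryocyte markers (median -0.03, adjusted p = 0.336), 12 epithelial tumour cell markers (median -0.03, adjusted p = 0.4) or 4 sex-linked genes (median 0.03, adjusted p = 0.879); at an unadjusted p under 0.05 these lists held 1, 0, 1 and 0 genes, and adjusted over each list alone 0. Xist, which is transcribed from the inactive X chromosome of females, read 13.04 ± 0.02 in both genotypes (n = 3 each).

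**Figure D3:**
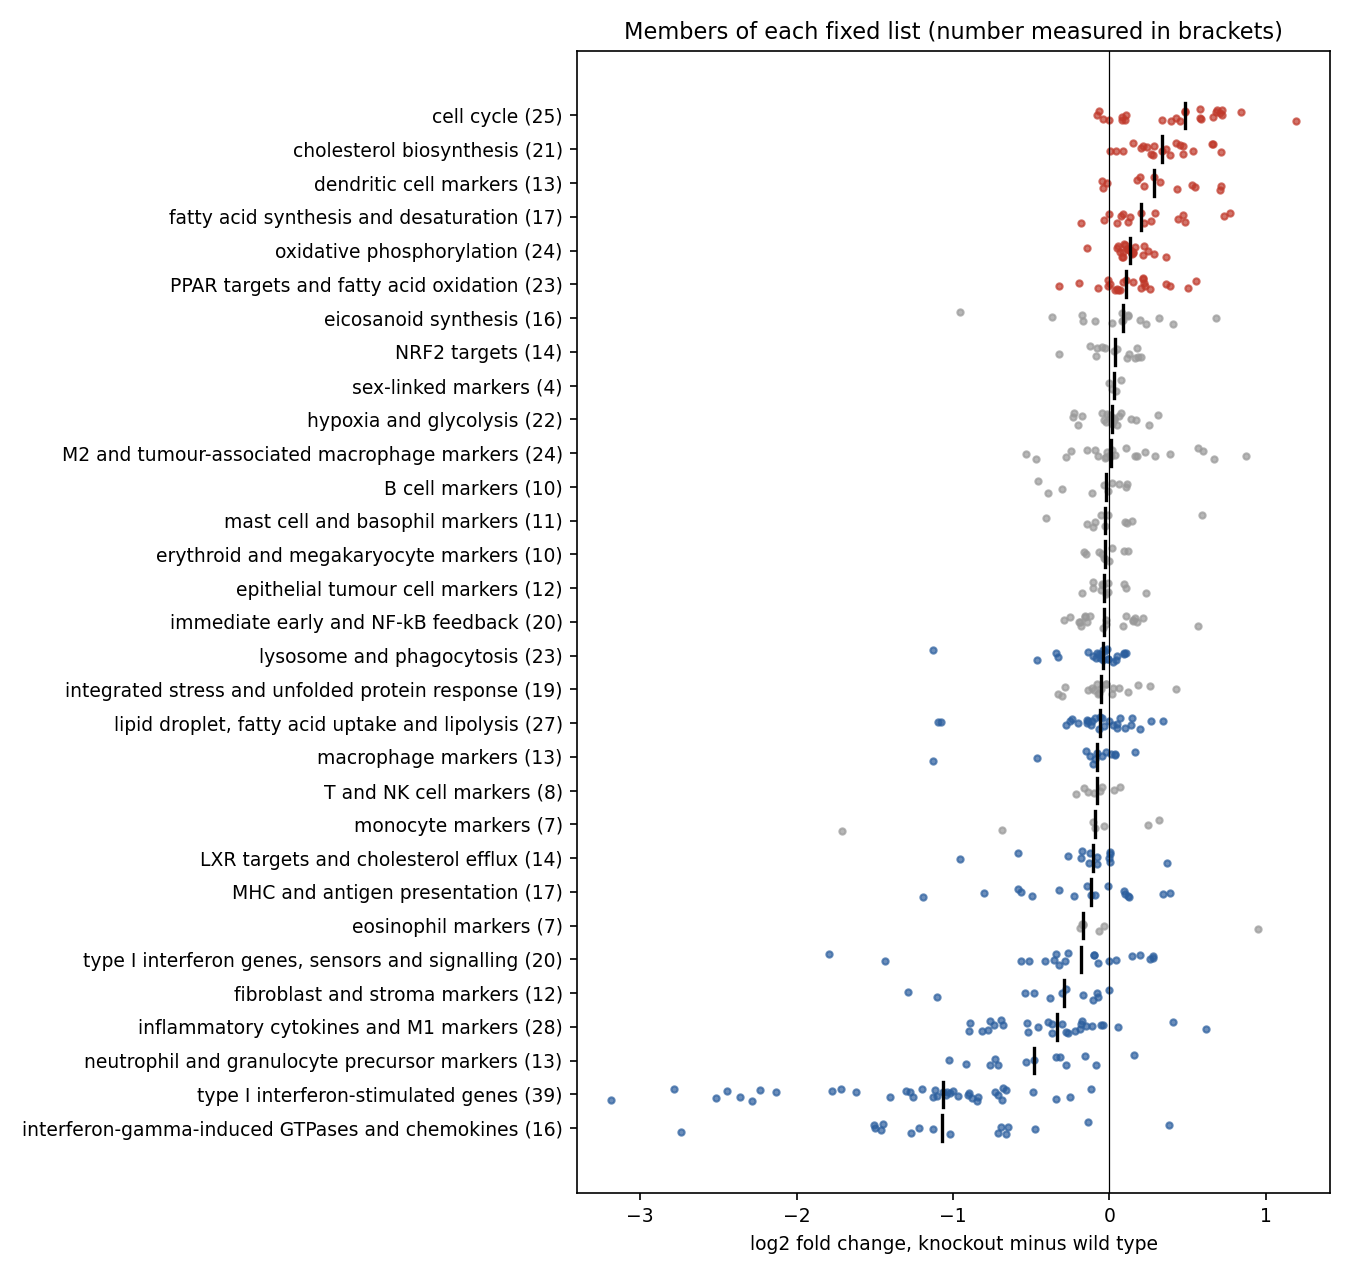
Log2 fold change (knockout minus wild type) of every measured member of the 31 fixed lists, with the number of members in brackets and a black bar at the list's median. Red lists were higher and blue lists lower at a camera adjusted p under 0.05 with the preset correlation, and grey lists did not pass; the medians run from -1.07 for the interferon lists to 0.48 for the cell cycle.

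The remaining gene lists did not pass with camera in the planned fit of all probe sets. Hypoxia and glycolysis genes had a median of 0.02 and a mean of 0.01 over 22 genes, with the direction lower in camera and higher in fry (camera adjusted p = 0.914); 0 genes passed limma's threshold, 1 was higher and 1 lower at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. NRF2 targets had a median of 0.04 over 14 genes (adjusted p = 0.821), with 0 genes past limma's threshold, 3 higher and 1 lower at an unadjusted p under 0.05, and 0 adjusted over the list alone. Among 16 eicosanoid synthesis genes (median 0.08, adjusted p = 0.332), the leukotriene C4 synthase gene Ltc4s (0.68, SE 0.12) and the prostaglandin E receptor gene Ptger4 (0.32, SE 0.07) rose, and Ptges, a prostaglandin E synthase gene, fell by 0.96 (SE 0.18); adjusted over the list alone, 3 rose and 1 fell. The number that rose was 0 without knockout replicate 1, knockout replicate 2, wild-type replicate 1 or wild-type replicate 2, and 1 without knockout replicate 3. Among 19 genes of the integrated stress and unfolded protein response (median -0.05, adjusted p = 0.232; median -0.06, adjusted p = 0.0473 with above-median probe sets only), Ppp1r15a fell by 0.33 (SE 0.07), with 3 lower and 2 higher adjusted over the list alone. Among 20 immediate early and NF-kB feedback genes (median -0.03, adjusted p = 0.305), Egr3 rose by 0.57 (SE 0.13), and adjusted over the list alone 1 rose and 1 fell. Ppp1r15a lost its call without each of the 6 arrays in turn, and Egr3 and Ptges without each except knockout replicate 3.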

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

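Fabp5 stayed lower and past the threshold under every alternative run, from -6.10 to -7.03, and no list or gene named by the fixed rule and past the threshold changed direction; genes chosen later were not run under all alternatives. The number of called probe sets (1691, with 927 higher and 764 lower) moved more than the directions. It was 2692 (1715 higher) when only probe sets above the median level were tested, 3126 (2050 higher) with trend and robust settings, 3775 (2259 higher, 1516 lower) at an adjusted p under 0.1 and 171 (14 higher, 157 lower) at a log2 fold change of at least 1. The mean of a gene's probe sets, which tests genes, gave 1243 (761 higher, 482 lower), against 519 higher and 373 lower with 1 probe set per gene. The floor gave 71 (52 higher, 19 lower); it left 7407 probe sets without any spread, and limma's prior degrees of freedom were 0.47 in place of 5.04. Leaving out each array in turn gave 40 to 1360 called (24 to 618 higher, 16 to 742 lower), lowest without knockout replicate 1 and highest without knockout replicate 3. Each of these fits has 1 array fewer. Without knockout replicate 1 the interferon-stimulated list's median was -1.11, so its lost calls did not come with a smaller shift. Knockout replicates 2 and 3, which then remain, had the lowest r within a genotype (0.9965). Why the arrays differ in this was not tested further. Quantile normalization gave 686 higher and 817 lower, and median centring 1155 and 762, so whether rises or falls are more numerous depends on scaling. With the replicate number as a block (replicate block), 92 were called (49 higher, 43 lower) and 65 of the 75 called genes other than Fabp5 lost their call. Arrays of the same number deviated with correlations of -0.06, -0.04 and -0.13, and 0 of 6 lay closest to their own number. These normalized values thus show no deviation shared by number, but cannot tell whether arrays of a number were handled together. Trend and robust settings left 6 of 39 interferon-stimulated genes called, against 33, and the floor and the block left 0 (limma; 36 and 37 at an unadjusted p under 0.05). That list's median, -1.07, ran from -1.29 to -0.83 without each array and passed camera each time. The list did not pass with an estimated correlation (median -1.07, adjusted p = 0.292) or with fry (median -1.07, adjusted p = 0.0522). Its genes' estimated correlation was 0.90, against the preset 0.01, so the preset p-value treats them as nearly independent, which they were not. The estimates for the cell cycle and interferon-gamma lists were 0.54 and 0.53. For the fibroblast list the estimate was -0.02, under the preset value, and it lost its call too (camera adjusted p = 0.15). The 2 camera settings thus differ in more than the correlation. Why fry did not pass was not tested. Of the 31 lists, 17 were called, 0 with camera and an estimated correlation (4 at an unadjusted p under 0.05) and 6 with fry. Fry's 6 were the fibroblast, interferon-gamma and MHC lists (lower) and the cholesterol, fatty acid synthesis and oxidative phosphorylation lists (higher). The inflammatory (fry adjusted p = 0.0653), cell cycle (0.0881), dendritic cell (0.107) and neutrophil (0.113) lists did not pass with fry. Of the 16 called lists besides the interferon-stimulated one, 11 kept the call under all alternatives but fry and the estimated correlation. Of the 75 genes 0 kept it under all alternatives, mainly through the floor (74 lost) and knockout replicate 1 (72 lost). No signal over background was available per probe set, which limits what can be said of dim genes.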

Other observations

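The gene groups of the next paragraph, Nnt, the grouping of the spikes, the test of Ifnb1 and the test of genes near Fabp5 were chosen only after the results were seen; the other tests were not.

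Of 9 measured fatty-acid-binding protein genes other than Fabp5 (median -0.09), 3 fell, 0 rose and 6 did not pass. Those that fell were Fabp3 (-1.10, SE 0.13), Fabp4 (-1.08, SE 0.11) and the brain-type gene Fabp7 (-0.95, SE 0.07, n = 3 per genotype, limma adjusted p = 0.00278). Fabp7 passed without each array in turn (limma adjusted p at most 0.0298), and Fabp3 did not without knockout replicate 1 (0.0611) or wild-type replicate 2 (0.0520). Whether the probes of these 3 genes also bind the related Fabp5 transcript was not tested, so their falls need not be changes of their own transcripts. Among 14 heat-shock chaperones, the inducible Hspa1b (-1.27, SE 0.13, limma adjusted p = 0.0071) and Hspa1a (-1.21, SE 0.16) and the small chaperone Hspb1 (-0.65, SE 0.10) fell, 0 rose and 11 did not pass, with a median of -0.03. Hspa1b passed without each array (limma adjusted p at most 0.0463), but Hspa1a did not without knockout replicate 1 (0.0718) or wild-type replicate 2 (0.0603), and Hspb1 passed without 2 of the 6 arrays, knockout replicate 3 (0.0102) and wild-type replicate 3 (0.0436). Among 10 genes of serine and one-carbon metabolism, the mitochondrial enzyme gene Shmt2 rose by 0.81 (SE 0.08, limma adjusted p = 0.00705; at most 0.0369 without each array), 0 fell and 9 did not pass. Among 19 cytosolic aminoacyl-tRNA synthetases, Iars rose by 0.56 (SE 0.07, limma adjusted p = 0.0149; 0.0648 without knockout replicate 1), 0 fell and 18 did not pass.

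Nnt, the mitochondrial transhydrogenase gene that carries a deletion in some C57BL/6 substrains, was chosen after its values were seen. It was higher in knockout on 2 of 3 probe sets, by 0.92 (SE 0.20, limma adjusted p = 0.0392) and 0.78 (SE 0.18, limma adjusted p = 0.0494), and differed by 0.02 (SE 0.08) on the dimmest. The brighter probe set passed without knockout replicate 2 (limma adjusted p = 0.0484) or wild-type replicate 3 (0.0416), and not without any other array (highest 0.128). Tmem267, among the largest rises named above (1.28, SE 0.24, limma adjusted p = 0.0269), lies on chromosome 13, as Nnt does. The labels give no substrain, so a difference in background between the genotypes cannot be told apart from an effect of the knockout for these genes.

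The interferon-stimulated genes, lower in knockout by a median of -1.07, were the broadest fall. A single array does not set that shift: the median nearest to 0 was -0.83, without knockout replicate 2, although the count of called genes depends on single arrays. Dilution of macrophage RNA by cells that lack the macrophage markers is argued against by these markers, whose median was -0.078 and lower quartile -0.12. Cells that express many of them, as the dendritic cells of such a culture may, would escape this test. Fcgr1 and Mertk of the list did fall. A lower interferon beta transcript stays open as a hypothesis: Ifnb1 differed by -1.43, with all 3 knockout arrays below the wild type. That size may be a lower bound, as the knockout mean is under the median of all values. But Ifnb1 is itself raised by interferon signalling, so these values may be a part of the pattern and give it no order. The genotype, which the design names, stays open as well, and rescaling the deposited values left the median at -1.06 (quantile normalization) and -1.05 (median centring).

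The cell cycle genes, higher in knockout by a median of 0.48, moved with the dendritic cell markers. A single array does not set the shift, since the median nearest to 0 was 0.35, without knockout replicate 2. A larger share of another cell type stays open: 1 list of another cell type, the dendritic cell markers, was higher in knockout, with an adjusted p of 0.414 once the correlation was estimated. Its most abundant genes, chosen here after their values were seen, read 13.25 against 12.97 for Cd24a and 13.15 against 12.60 for Fscn1. In wild type 11 of its 13 genes lay above the median level, which does not by itself show that a gene is expressed. Of the 13 genes, 1 also stands on another list, and the labels name no sort or gate. Neutrophil markers (-0.48) and fibroblast markers (-0.29) went the other way, so a lower share of macrophages with all other cells in proportion is argued against, and a change of state within the macrophages was not tested apart from the genotype.

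Genes near Fabp5 were called at a higher rate than others, without passing a test. Within 10 Mb of Fabp5 in the RefSeq table, 5 of 47 genes were called (10.6%), among them Fabp4, Car13 (-0.68, SE 0.09), Zc2hc1a (-0.42, SE 0.08) and Zfand1 (0.37, SE 0.07), against 4.90% of 17984 elsewhere. Sequence of another strain left around a targeted gene could give such a cluster. The odds ratio was 2.31 (95% interval 0.71 to 5.85; one-sided Fisher's exact p = 0.0795), so flanking sequence and an effect of the knockout cannot be told apart for these genes with so few of them. Of those named, Fabp4 passed without each array in turn, Car13 without 4 of the 6, and Zc2hc1a and Zfand1 without 1 each.

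The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05; the real split gave 1691 called probe sets, the highest of the others 0, and 1 of the 10, the real one, gave as many as the real one. Of 64 control probe sets, 0 differed between genotypes in limma at an adjusted p under 0.05, and 1 did at an unadjusted p under 0.05. All 24 probe sets of the poly-A spikes, transcripts added before labelling, had the higher mean in knockout, by 0.05 to 0.31 (median 0.14). These probe sets stand for 4 transcripts, so their signs are not independent. The genotypes overlapped: the mean deviation was 0.04, 0.06 and 0.11 in knockout replicates 1, 2 and 3 and 0.12, -0.03 and -0.30 in wild type. Of 18 hybridisation spikes, 7 were higher and 11 lower (median -0.01), and whether the amount of RNA differed was not tested.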
